A study of Mus musculus with 2 samples.

How the data were processed

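Histone H3 monomethylated at lysine 4 (H3K4me1), a mark of enhancers and of the flanks of promoters, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in lung tissue of newborn mice. The 2 samples formed 1 group of 2 biological replicates, each made from tissue pooled from males and females at postnatal day 0, and the labels give a pool of 15 mice for replicate 1. A library size range of 300 to 500 is given in the labels for both replicates.

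The authors deposited 4 peak lists in the narrowPeak format on mouse build mm10, per the files' descriptions: 1 list for each replicate, 1 called on both replicates together (the pooled list) and 1 named replicated peaks, derived from the other 3. The peak caller, the aligner, their versions, the control libraries and the rule behind the replicated list are not given in the sources used here. Each deposited peak has a signal value, an enrichment measure whose reference is not stated. Each also has a −log10 p and a −log10 q as the authors' peak caller gave them. These values were used only to describe, rank or filter peaks within a list. Because peaks were called separately in each replicate, a peak missing from 1 list shows only that it was not called there. The lists hold no read counts, so the depth of both libraries is unknown, and a difference in depth alone can change the number and width of called peaks.

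Positions were compared with the GRCm38 sequence, the same build as mm10, and the GENCODE M21 annotation. The lists held peaks on 20 chromosomes, and all peaks ended within the chromosome lengths of this build. The annotation gave 21829 protein-coding genes, each placed at its most upstream coding TSS, and 54327 distinct coding TSSs in all. Analyses were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

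Peaks of the replicates were called shared when they overlapped by at least 1 bp. The shared fraction was compared with 1000 random circular shifts of the other list within each chromosome, with N runs removed (one-sided permutation test). Each peak was assigned by its centre to a promoter (within 1 kb of a coding TSS), else an exon, an intron or the space between genes, and the shares were compared with 1000 shifts (two-sided permutation test). The smallest p these permutations can give is 0.000999 one-sided and 0.002 two-sided. For each gene, bases covered by peaks within 20 kb either side of its TSS were summed. Such a window can hold other genes, so the covered bases need not belong to the named gene. The median of each of 18 gene lists was compared with 10000 random lists of the same size, matched on the number of coding TSSs within 20 kb (two-sided permutation test, Benjamini-Hochberg adjustment over the 18 lists, threshold 0.05). Distal peaks, with centres over 1 kb from any coding TSS, were searched over their central 500 bp for 12 consensus motifs on either strand. They were compared with as many random 500-bp windows outside all lists, matched on GC content, by Fisher's exact test with Benjamini-Hochberg adjustment over the 12 motifs. Peaks, genes and windows are not biological replicates, so these p-values and intervals describe the 2 deposited libraries and not the spread between animals.

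To compare the replicates at equal list length, the longer list was thinned to the 72783 peaks with the highest −log10 p. Genes named in the text were the members of each list with the most (up to 4) and the fewest (up to 2) covered bases, the 25 genes with the most covered bases of all genes, the 5 peaks with the highest signal value, and the 5 genes on each side with the largest difference between the thinned replicates. In the ranking of all genes and in the replicate difference, a gene within 40 kb of one already taken was skipped. The gene lists, motifs, tests, naming rule and most alternatives were fixed before the data were examined. Alternatives covered the overlap rule, stricter peak thresholds, the pooled list, each replicate's own list, the windows, the matching of random lists, the motif background and the merging of nearby peaks.

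The tests were tested on simulated data. With 30.1% of 19902 simulated peaks placed on another list, 30.3% were found to overlap. With 19.9% of 19944 simulated peaks placed on promoters, 22.0% were assigned there, and 2.72% of randomly placed peaks were. When 1000 bp was added to each of 14 random genes among the 21829, 70.0% of 200 simulated lists were called above random at an unadjusted threshold. With 2000 bp added 100% were called, and with nothing added 2.50% were called above and 0% below. A FOX site was planted in 437 of 8742 random windows, and the consensus was found in 1003 windows, the number expected from planted and existing sites together.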

Results

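H3K4me1 was profiled in newborn mouse lung at postnatal day 0, in 2 biological replicates of 1 group, each from tissue pooled from both sexes. The labels state no comparison between conditions, so the replicates were compared with each other and the peaks described along the genome. The depth of the libraries is unknown.

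Replicate 1 held 154776 peaks and replicate 2 held 72783. The peaks of replicate 1 covered 60.4 Mb, or 2.28% of the sequenced genome, with a median width of 300.0 bp. Those of replicate 2 covered 19.8 Mb, or 0.749%, with a median width of 231 bp. The median deposited −log10 p was 4.78 in replicate 1 and 4.00 in replicate 2, and 89.5% and 22.7% of the peaks, respectively, had a deposited q of at most 0.05. The pooled list held 108729 peaks over 40.7 Mb, and the replicated list 51880 peaks over 25.9 Mb with a median width of 413 bp. Merging peaks closer than 1 kb left 87770 regions in replicate 1 and 62936 in the pooled list.

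Peaks of the replicates overlapped far more often than after random shifts, which keep the spacing of peaks but not their relation to genes or GC content. Of the replicate 2 peaks, 58.9% overlapped a replicate 1 peak, against 4.17% ± 0.180 (SD over 1000 shifts) after shifting, a ratio of 14.1 (one-sided permutation p = 0.000999, the smallest possible). In the other direction 25.6% of replicate 1 peaks overlapped replicate 2, against 1.95% after shifting, a ratio of 13.2 with the same p. Sharing was highest among the peaks of highest rank. In replicate 2 it was 82.9% in the highest 10% by −log10 p, and over the lower 60% it lay between 45.0% and 55.3% with no steady order. In replicate 1 it rose at each step from 13.0% in the lowest 10% to 58.8% in the highest. Of all bases covered in either replicate, 14.5% were covered in both. Across 255946 bins of 10 kb, which are not independent replicates, covered bases correlated with a Pearson r of 0.792 and a Spearman rho of 0.622. With both peaks required to overlap by at least 50% of their length the shared fraction of replicate 2 was 20.7%, and with replicate 1 thinned to the length of replicate 2 it was 42.3%.

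**Figure D1:**
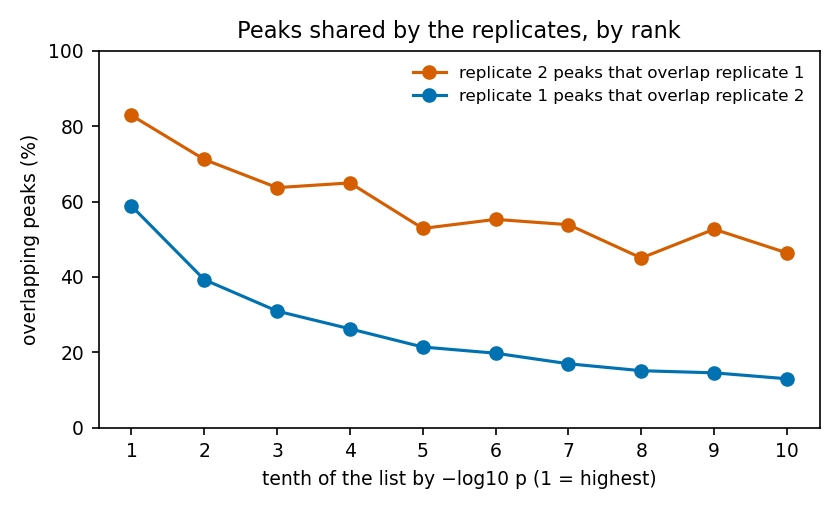
Share of peaks (%, y axis) that overlap a peak of the other replicate by at least 1 bp, in 10 equal parts of each list ranked by deposited −log10 p (x axis, 1 is the highest part), for replicate 2 (orange) and replicate 1 (blue). The share in replicate 2 is 82.9% in the highest part and 46.4% in the lowest, and in replicate 1 58.8% and 13.0%.

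All 51880 replicated peaks had the coordinates of a pooled peak. Of them 36574 (70.5%) overlapped a peak of both replicates, 14862 (28.6%) overlapped replicate 1 alone, 416 (0.802%) replicate 2 alone, and 28 neither replicate. The replicated list is therefore not limited to peaks called separately in both replicates.

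The 5 replicated peaks with the highest signal value lay in or near Ptpa, Dab2ip, Ski, Ccr10 and Ergic1. The highest, at 7.44, was at chromosome 2, 30442105 to 30443481 (mm10), inside Ptpa, a phosphatase activator gene, with its centre 58 bp from an annotated TSS. The next, at 7.02, was in an intron of Dab2ip on chromosome 2, 35680814 to 35682652. A peak with a signal of 6.88 lay between genes on chromosome 4, 155233225 to 155235353, 11.7 kb from the TSS of Ski, a regulator of TGF-beta signalling. Peaks with a signal of 6.60 lay in an exon where Ccr10 and Cntnap1 overlap on chromosome 11, 101172957 to 101173615, and in Ergic1 on chromosome 17, 26600844 to 26602632, 413 bp from a TSS.

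Promoters and introns held more replicated peaks than after random shifts, and the space between genes held fewer. Promoters held 10058 peaks (19.4%), against 2.68% ± 0.138 (SD over shifts) after shifting. Introns held 53.2% against 37.4%, exons 3.42% against 2.56%, and the space between genes 24.0% against 57.4% (two-sided permutation p = 0.002 for each, the smallest possible). The promoter share was 13.4% in replicate 1 and 15.4% in replicate 2. Within 2.5 kb of a TSS the share was 31.6%.

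H3K4me1 peaks flanked TSSs and covered the TSS itself less often. Of 21829 coding TSSs, 4.27% were covered by a replicated peak at the TSS, 8.79% at 500 bp upstream and 13.9% at 900 bp downstream. Coverage at the TSS was thus 0.486 of the highest upstream value and 0.307 of the highest downstream value. These ratios were 0.461 and 0.345 in replicate 1 and 0.694 and 0.479 in replicate 2, so the dip was present in both lists and shallower in replicate 2, with 1 library on each side.

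**Figure D2:**
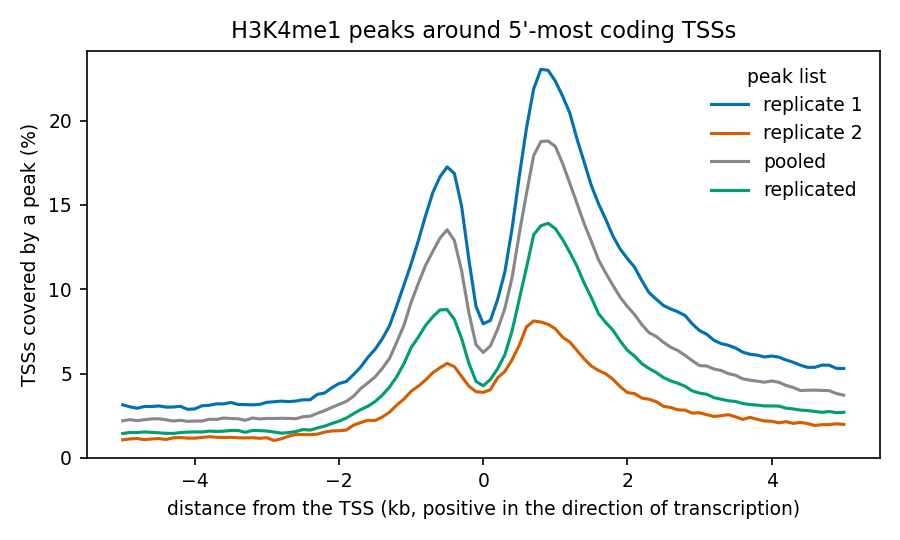
Share of 21829 coding TSSs covered by a peak (%, y axis) against distance from the TSS (kb, x axis, positive in the direction of transcription), one line for each peak list. All 4 lines dip at the TSS, with replicated peaks at 4.27% there and at 13.9% at 900 bp downstream.

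Genes of alveolar type II epithelium and of lung development signalling had more H3K4me1 around them than random lists. Alveolar type II genes, of the surfactant-producing cells, had a median of 1742 bp covered by replicated peaks within 20 kb of the TSS, against 361 bp in random lists (adjusted permutation p = 0.0468). The signalling genes of lung development had a median of 1516 bp against 278 bp (adjusted permutation p = 0.0144), and 16 of the 18 lay above the median of all genes, 437 bp. Both lists also passed in each replicate's own list. Neither passed when random lists were matched also on the GC content around the TSS, an alternative chosen after seeing the data (adjusted permutation p = 0.217 for both), with random medians of 780.5 and 819.5 bp. With windows of 5 kb type II genes turned direction, with a median of 0 bp against 109 bp in random lists (adjusted permutation p = 1), and signalling genes did not pass (0.164). Neither passed with windows of 100 kb (adjusted permutation p = 0.404 and 0.130) or without matching on gene density (0.0864 and 0.0792), where random medians were 436.5 and 443.5 bp. Type II genes also did not pass with the top 50% of peaks by −log10 p (0.471), the mean of the list (0.377) or the gene body with 10 kb (0.110).

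Among type II genes, Lpcat1, an enzyme of surfactant lipid synthesis, had 3085 bp, Napsa, a protease that processes surfactant protein, 3039 bp, Cebpa 2735 bp, and Sftpb, encoding surfactant protein B (chromosome 6, 72304610 to 72314371), 2697 bp. Slc34a2 and Lamp3 had 0 bp. In replicate 1's own list Slc34a2 had 594 bp, and in replicate 2's 0 bp, while Lamp3 had 0 bp in both. Among the development genes, Notch1, a receptor gene (chromosome 2, 26457903 to 26516663), had 8494 bp, Spry4, a feedback inhibitor of FGF signalling, 6601 bp, Fgfr2 5638 bp, and the hedgehog receptor gene Ptch1 4968 bp. Shh had 0 bp and Gli3 214 bp. In replicate 1's own list Shh had 2909 bp, and in replicate 2's 406 bp.

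Alveolar type I genes, of the thin gas-exchange cells, had a median of 1497.5 bp against 325 bp in random lists and did not pass over the 18 lists (adjusted permutation p = 0.0756). They passed in replicate 1 (adjusted permutation p = 0.0096), in replicate 2 (0.0372) and in the pooled list (0.0300), as well as with peaks of −log10 p of at least 5 (0.0300), with the mean of the list (0.0414) and with replicated peaks that overlap both replicates (0.0432). They did not pass with matching also on GC content (adjusted permutation p = 0.217), windows of 5 kb (1) or 100 kb (0.404), the top 50% of peaks (0.178), the gene body with 10 kb (0.129), no matching on gene density (0.125), 1 gene per locus (0.0924) or autosomal genes alone (0.120). Hopx had 7427 bp, Ager, the receptor that marks type I cells, 7007 bp, Emp2 6168 bp and Clic5 2816 bp, and all 12 members had some coverage, down to 336 bp at Gprc5a and 659 bp at Pdpn.

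The other lists of lung cells did not pass. Airway epithelium had a median of 586 bp (adjusted permutation p = 0.640), with 5238 bp at the club cell gene Scgb1a1, 2625 bp at Foxj1, 2516 bp at Tppp3 and 0 bp at Scgb3a2. Scgb3a2 had 327 bp in replicate 1's own list and 0 bp in replicate 2's. Mesenchyme and smooth muscle had 759.5 bp (adjusted permutation p = 0.371), with 2158 bp at Tagln, 1343 bp at Foxf1 and 0 bp at Tcf21 and Col3a1. Tcf21 had 1714 bp in replicate 1's own list and 0 bp in replicate 2's, and Col3a1 had 0 bp in both. Endothelium had 300.0 bp (adjusted permutation p = 0.983), with 3117 bp at Plvap, 2826 bp at Gata2 and 0 bp at Cdh5 and Vwf. In the own lists of replicates 1 and 2, Cdh5 had 1949 and 190 bp, and Vwf 1373 and 746 bp. Mesothelium had 553 bp (adjusted permutation p = 0.775), with 1271 bp at Msln and 1209 bp at Wt1.

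None of the lists of blood and of tissues outside the lung passed. Immune cells had a median of 0 bp (adjusted permutation p = 0.477), although Cd68 had 5780 bp and Fcer1g 4225 bp. Erythroid cells had 142.5 bp (adjusted permutation p = 0.439), with Epor at 2966 bp and the X-linked Gata1 and Alas2 at 0 bp. The medians were 0 bp for hepatocytes (adjusted permutation p = 0.669), for gut and pancreas (0.640) and for germ cells (0.467). They were 238.5 bp for cardiac muscle (adjusted permutation p = 0.746), 415 bp for skeletal muscle (0.983) and 794.5 bp for neurons (0.439). For all of these lists at least 2.5% of random lists had a median of 0 bp, so the test had little or no room to call them below random. Ribosomal protein genes, with 1956.5 bp (adjusted permutation p = 0.120), anterior Hox genes, with 1465 bp (0.669), and posterior Hox genes, with 502 bp (0.380), did not pass. The 15 anterior Hox genes lie in 7 loci and the 16 posterior ones in 6, with windows that overlap, whereas random lists hold separate genes, so their p-values are too small. With matching also on GC content, posterior Hox genes passed below random lists (adjusted permutation p = 0.0072), but not with 1 gene per locus as well, chosen after seeing the data (0.236), and in replicate 2's own list they lay on the other side without passing, with 1868 bp against 880.5 bp (adjusted permutation p = 0.0590). Anterior Hox genes passed above random there (adjusted permutation p = 0.0423).

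**Figure D3:**
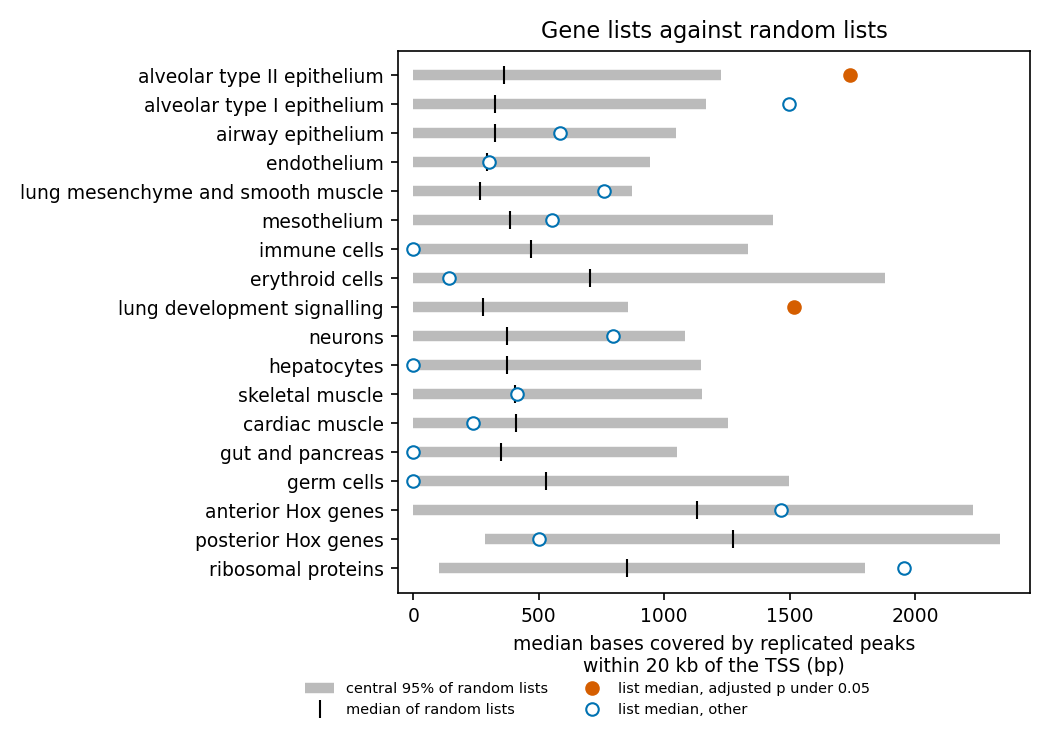
Median bases covered by replicated peaks within 20 kb of the TSS (bp, x axis) for each of the 18 gene lists (y axis), with the central 95% (grey bar) and median (black tick) of 10000 random lists. Filled orange points mark the 2 lists with an adjusted p under 0.05, at 1742 and 1516 bp, and open blue points the others.

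Among all genes, E030018B13Rik, Btg2 and Rara had the most covered bases. E030018B13Rik (chromosome 7, 63916857 to 63920539) had 20754 bp of the window covered, followed by the antiproliferative gene Btg2 (chromosome 1, 134075170 to 134079120) with 20658 bp and the retinoic acid receptor gene Rara (chromosome 11, 98927818 to 98974942) with 15886 bp. Basement membrane genes among the 25 were Lama5, with 15187 bp, and Hspg2, with 13347 bp. The thyroid hormone receptor gene Thra had 13192 bp. Bcar1, Actn4 and Myh9, which act in cell adhesion and the actin cytoskeleton, had 14936, 12234 and 12930 bp. Hdac5 had 14427 bp, Ski 13392 bp, Sdc4 13226 bp, Mcl1 13161 bp, and Socs3 12305 bp. Of all 21829 genes, 39.8% had no covered base.

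Distal peaks held FOX, TEAD, GATA and NFI motifs more often than background. Of 41766 distal windows, 8.60% held the FOX consensus TGTTTAC against 5.36% of GC-matched windows, a ratio of 1.60 (95% interval 1.52 to 1.69, Fisher's exact test, adjusted p = 8.64e-75). The ratio was 1.42 for TEAD (1.35 to 1.49, Fisher's exact test, adjusted p = 2.20e-47) and 1.31 for GATA (1.24 to 1.38, adjusted p = 3.96e-24). The full NFI site was in 70 windows against 12, a ratio of 5.83 (3.16 to 10.8, Fisher's exact test, adjusted p = 8.05e-11), and this ratio was 3.13 in replicate 2's own list, 3.07 in the pooled list and 3.68 with a background matched also on repeats. NKX2, the family of the lung factor NKX2-1, had a ratio of 1.199 (Fisher's exact test, adjusted p = 1.52e-12), and the E-box CAGCTG also 1.199 (adjusted p = 5.49e-61).

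AP-1, with a ratio of 1.13, ETS, with 1.09, and SOX, with 1.05, also passed, making 9 of 12 motifs. By the same exact test CTCF (1.21, adjusted p = 0.0789), HNF4 (1.08, adjusted p = 0.332) and NRF1 (0.667, adjusted p = 0.221) did not. Repeats made up 11.9% of the peak windows and 31.8% of the background. With a background matched also on repeats, chosen after seeing the data, AP-1 (exact test, adjusted p = 0.431) and SOX (0.256) no longer passed, while FOX had a ratio of 1.52 and TEAD 1.32. ETS did not pass among the replicated peaks that overlap both replicates, also chosen after seeing the data (exact test, adjusted p = 0.133), and SOX not in replicate 2 (0.435), whereas CTCF passed in each replicate's own list (1.26 and 1.80), in the pooled list (1.54) and against windows 5 kb away (1.30), and HNF4 in replicate 1 (1.18, exact test, adjusted p = 0.000275) and in the pooled list (1.23, adjusted p = 0.000236). With whole peaks the CTCF ratio was 0.790 (exact test, adjusted p = 0.0504), and against windows 5 kb away HNF4 had 0.929 and NRF1 1.69, none of which passed. The ETS ratio was 1.76 against those windows. The windows 5 kb away were not matched on GC content, unlike the other backgrounds, so ratios against them are not directly comparable with the others.

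The X chromosome held few peaks in every list. Replicated peaks covered 0.104 kb per Mb of X, against a median of 10.96 kb per Mb over the autosomes, which ranged from 7.25 on chromosome 3 to 18.6 on chromosome 11. The ratio of X to the autosomal median was 0.00952 in the replicated list, 0.0586 in replicate 1 and 0.0289 in replicate 2. No list had a peak on Y.

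**Figure D4:**
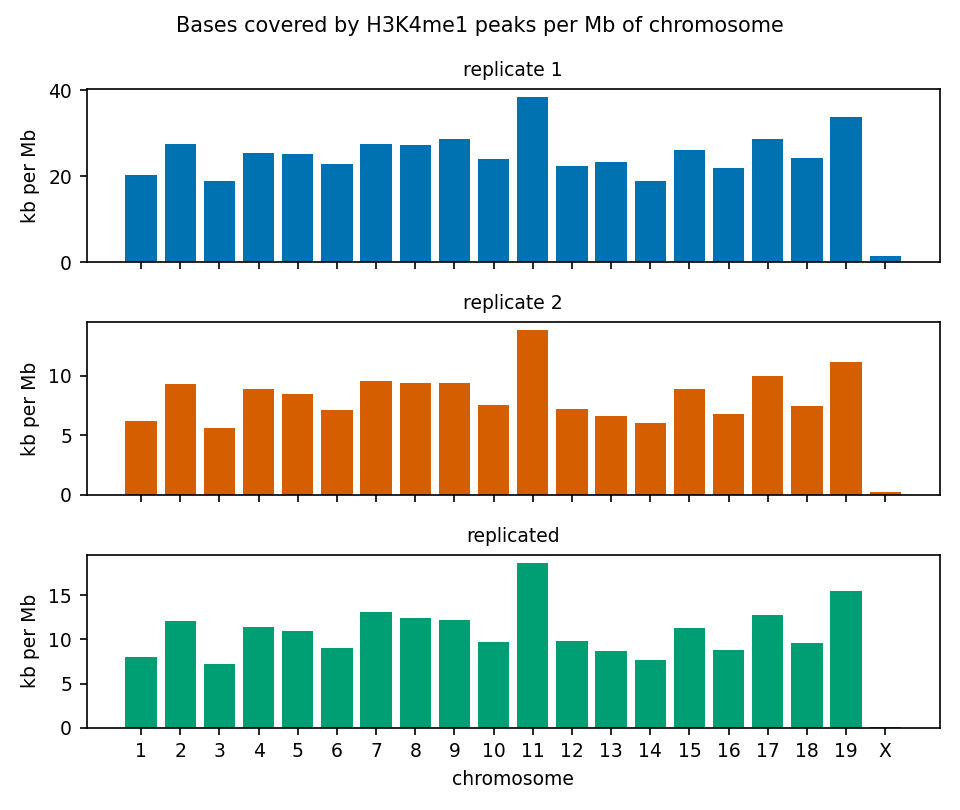
Bases covered by peaks (kb per Mb of chromosome, y axis) on each autosome and X (x axis) for replicate 1, replicate 2 and the replicated list. X stands far below every autosome in all 3 panels, at 0.104 kb per Mb in the replicated list against 7.25 on the lowest autosome.

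At equal list length the replicates differed in how broadly peaks covered genes. With 72783 peaks in each, replicate 1 covered 36.5 Mb and replicate 2 covered 19.8 Mb. Thinning kept replicate 1 peaks with a −log10 p of at least 4.82, and raised their median width from 300 to 400 bp. Replicate 2 was kept whole, with −log10 p down to 2.03 and a median width of 231 bp. Part of the difference in coverage may therefore come from the thinning. Per gene, replicate 1 minus replicate 2 had a median of 167 bp and an SD over genes of 1101 bp. Coverage was higher in replicate 1 for 12046 genes and in replicate 2 for 3815, with no replicate check of either direction. With the lists as deposited the median was 736 bp.

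Higher in replicate 1 were E030018B13Rik, with 24042 against 11326 bp, Btg2, with 22569 against 10723 bp, Abhd17c, with 14828 against 3467 bp, Actn4, with 15682 against 4925 bp, and Ptpn1, with 14994 against 4321 bp. Higher in replicate 2 were Foxf1, Prdm12, Hoxb7, Sp8 and Dlx1, which encode transcription regulators of development. Foxf1, needed for lung mesenchyme (chromosome 8, 121084386 to 121088144), had 0 against 3606 bp, Prdm12 0 against 2904 bp, Hoxb7 712 against 2959 bp, Sp8 0 against 2197 bp and Dlx1 1307 against 3408 bp. In replicate 1 as deposited, before thinning, Foxf1 had 3254 bp, Prdm12 968 bp, Hoxb7 1493 bp, Sp8 971 bp and Dlx1 2732 bp. Of the peaks called only in thinned replicate 1, 14.2% lay in promoters and 2.46% in exons. Of the replicate 2 peaks that overlapped no peak of thinned replicate 1, 12.03% lay in promoters and 4.72% in exons. With the lists as deposited, 29925 replicate 2 peaks overlapped no replicate 1 peak, with 9.89% in promoters and 4.99% in exons. In the other direction there were 115105 replicate 1 peaks, with 11.2% in promoters and 2.67% in exons.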

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

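The alternatives that required overlap with both replicates, 1 gene per locus, autosomal genes, GC matching of gene lists (alone and with 1 gene per locus), and repeat matching of motif windows were chosen after seeing the data. The overlap of the replicates and the promoter share kept their direction and stayed past the threshold under every alternative run, at 20.7% to 60.5% and 13.4% to 31.6%. Between 7 and 11 motifs were enriched and none was depleted in any setting. The number of gene lists above random was 2 and depended on the setting. It was 1 with the top 50% of peaks by −log10 p, 0 with a window of 5 kb, 0 with a window of 100 kb, 1 with the gene body and 10 kb, 1 without matching on gene density (ribosomal proteins instead), and 0 with GC matching, which also put 1 list below random, and 0 with GC matching and 1 gene per locus, with 0 below. Without replicate 1 or replicate 2 it was 3 to 4. With GC matching the random median rose from 361 to 780.5 bp for type II genes and from 278 to 819.5 bp for lung development signalling, and for the other settings the cause was not tested. The correlation over bins was 0.917 with 100-kb bins, and 69.4% of replicated peaks overlapped both replicates at 50% of either peak. The TSS ratios ranged from 0.461 to 0.694 upstream and 0.345 to 0.479 downstream without replicate 1 or replicate 2. The X ratio ranged from 0.0289 to 0.0586 there. The median replicate difference was 736 bp with the lists as deposited and 1321 bp with a window of 100 kb. Merging peaks closer than 1 kb left 87770 in replicate 1 and 62936 in the pooled list. Among single results for gene lists, 212 kept their direction and their side of the threshold, 9 passed newly, 12 no longer passed and 37 changed direction. For motifs these numbers were 69, 6, 4 and 5. None of the results that changed direction passed under the alternative. Their percentiles among random lists follow by setting. In the pooled list skeletal muscle was at 29.6. With the top 50% of peaks airway was at 32.4, skeletal muscle at 27.1 and anterior Hox at 20.4. With the window of 5 kb type II was at 23.8, skeletal muscle at 22.8 and anterior Hox at 14.9. With 100 kb airway was at 30.2, mesothelium at 44.3, erythroid at 83.1, neurons at 49.1, cardiac muscle at 91.6, germ cells at 50.045 and posterior Hox at 71.8. Without density matching endothelium was at 31.8, skeletal muscle at 45.9 and posterior Hox at 56.5. With the mean of the list endothelium was at 44.7, mesenchyme at 49.2, mesothelium at 29.7, skeletal muscle at 31.3 and anterior Hox at 40.4. With overlap of both replicates cardiac muscle was at 52.0, and with autosomal genes endothelium was at 42.9 and skeletal muscle at 45.1. With GC matching airway was at 49.98, endothelium at 11.9, mesothelium at 38.6, skeletal muscle at 10.7 and anterior Hox at 34.3. With 1 gene per locus as well endothelium was at 12.045, mesothelium at 37.6, skeletal muscle at 6.73 and anterior Hox at 44.01. Without replicate 1 or replicate 2, posterior Hox ranged from 18.3 to 99.2, cardiac muscle from 31.3 to 68.7 and skeletal muscle from 35.5 to 51.6. Among motifs, the CTCF ratio was 0.790 with whole peaks. Against windows 5 kb away, which were not matched on GC content, HNF4 had 0.929 and NRF1 1.69. NRF1 had 1.07 with overlap of both replicates and 1.11 with repeat matching. The unknown depth limits every comparison of peak numbers between the replicates.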

Other observations

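The gene groups in the next paragraph were prompted by the genes with the most covered bases, and written down without those genes before their values were tested. The tests of signal on the X chromosome were set only after signal values on X had been seen.

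Immediate early genes, which respond to stimuli within minutes, had a median of 3681 bp covered by replicated peaks within 20 kb of the TSS, against 476 bp in random lists (permutation p adjusted over 4 groups 0.0004). Junb had 8990 bp, Ier3 5920 bp and Nr4a1 5847 bp, and 17 of 18 members had coverage. Focal adhesion and actin genes had 3354 bp against 358 bp (adjusted permutation p = 0.0004), with Itga3 at 9564 bp, Pxn at 6953 bp and all 23 members covered. Basement membrane genes had 1645 bp against 336 bp (adjusted permutation p = 0.000800), with Tinagl1 at 8279 bp and Lamb1 at 5567 bp. Retinoid signalling genes, at 743.5 bp against 377 bp, did not pass (adjusted permutation p = 0.253). High mean GC content within 20 kb of the TSS does not account for all of the excess in the first 3, but may account for part. Matching also on it raised the random medians to 1182.5 bp for immediate early, 912 bp for focal adhesion and 622 bp for basement membrane genes. Against these matched lists, the medians of the 3 groups stayed in the upper 2.5%. That upper 2.5% began at 2190 bp for immediate early, 1694 bp for focal adhesion and 1227 bp for basement membrane genes. Broad expression of such genes may contribute, as no expression data were used here and no biological explanation was tested.

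X was nearly empty of peaks, and a lower dose of X in tissue pooled from both sexes is a candidate explanation for part of it. Sequence content alone does not account for all of it: in 100-kb bins matched on GC, repeats and TSS number, the ratio of X to autosomal covered bases rose from 0.0598 to 0.193 in replicate 1 and from 0.00984 to 0.0389 in the replicated list, so content may account for a part. The 90th percentile of signal over X peaks was 0.895 of that over as many autosomal peaks from like bins in replicate 1 (3.45, against 3.79 to 4.05 in the central 95% of 1000 draws) and 0.917 in replicate 2 (3.44, against 3.67 to 4.07). A lower dose could lower the signal in this way unless the signal is relative to a matched control. The reference of the signal is not stated. Fewer sites with a larger share of calls near the threshold could also lower it. In replicate 2, 94.4% of X peaks had a q over 0.05 against 77.2% on autosomes (15.6% against 10.4% in replicate 1). These explanations therefore cannot be told apart, and a filter or scaling of X in the authors' processing also stays open.

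Compared with thinned replicate 1, replicate 2 gave a larger part of its covered bases to developmental transcription factor genes. The test covered 112 loci of homeobox, T-box and related genes, without the 5 genes that prompted it. Of the bases covered there in thinned replicate 1 and replicate 2 together, 53.0% came from replicate 2. The share was 35.7% in random lists (permutation p = 0.0002, the smallest possible). Coverage was higher in replicate 2 at 68 loci and in thinned replicate 1 at 39. A chance choice of genes is thus argued against, though loci that prompted the test may add to the share. The 5 genes were left out by name, so neighbours with overlapping windows, such as Dlx2 beside Dlx1, may have stayed in. Mean GC content within 20 kb of the TSS does not account for the larger share of replicate 2, as the upper 2.5% of lists matched on this content began at 40.1%. GC content at the peaks themselves was not matched. It was 48.7% for peaks of only replicate 2 and 47.4% for peaks of only thinned replicate 1. With the 20000 peaks of lowest p in each replicate the share was 58.0%, against 32.2% in random lists. The larger share thus did not need the replicate 2 peaks of lower rank. A part of weak peaks is not excluded, as only 22.7% of all replicate 2 peaks had a q of at most 0.05, and the cut still held others. That cut also drops weaker replicate 1 peaks, as the thinning does. The share was not computed for the lists as deposited, so a loss of those replicate 1 peaks stays open. A difference in tissue composition, immunoprecipitation or depth between the pools stays open, with 1 library on each side.

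The peaks of replicate 2 with the lowest p lay over a ribosomal RNA copy on chromosome 17. They were at 39848258 to 39848858 and 39843383 to 39843708, with signal values of only 1.92 and 1.88. Further replicate 2 peaks over this copy ranked from 815 to 49098 by p, and replicate 1 had no peak there. The replicated list had 1 peak over this copy, at 39848326 to 39848654, inside the replicate 2 peak of lowest p, with a signal of 1.23. The cause was not tested.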
